A study of Mus musculus with 82 samples.

How the data were processed

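The study grew mouse embryonic stem cells of a hybrid background of inbred strains. Per the labels' protocols, each ChIP used 10000000 crosslinked cells, and 1% of the chromatin was kept as input. For tagged proteins the chromatin was sonicated to fragments averaging 300 bp, and the FlagAvi tag, which can be biotinylated, was captured on streptavidin beads. For H3K9me3 it was cut with micrococcal nuclease and captured with an antibody. Per the submitters' processing notes, the series was processed with bcl2fastq 1.17, Bowtie 1.0.0, STAR 2.5.0a, edgeR and MACS2 on mm10 (GRCm38); the notes give these tools no roles, and caller settings and filters are not given in the sources used here.

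The values used here are 2 peak lists without header lines, each pooled over replicates by the authors. The Adnp list holds start, end, name and, in the deposited file, a score per peak by the authors whose kind is not stated; it ran from 3.66 to 565 over 4503 distinct values and was used only to describe and rank peaks within the list. The score is 0 for every peak of the HP1γ list as deposited, so those peaks were not ranked. The peak names of the Adnp list are numbered up to 31188 while 15026 peaks are listed, and those of the HP1γ list up to 2701 while 2047 are listed, so both are subsets of longer lists. The names of the HP1γ peaks point to the Adnp knockout and the series description ties the list to both genotypes, so which genotype a peak was seen in is not known here. Neither list gives counts or depth. The precision of a share follows from its number of peaks, and 95% Wilson intervals (shares) or exact Poisson intervals (peaks per Mb) cover counting error only. Peaks are not replicates, neighbouring peaks are not independent, and p-values describe these lists.

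Genes came from a table of the GRCm38.p6 assembly with 49997 genes, their starts and ends and their types. It holds no strand, exons or sequence. The planned comparisons with transcription starts were therefore made with gene ends, meaning either end of a gene, and the planned comparisons with exons, motif words, repeats and base composition were not run. Genes on chromosomes 1 to 19 and X starting at 3 Mb or later were used (49214 genes, 21523 of them protein coding); 340 genes with lower positions, which belong to scaffolds, and 443 genes elsewhere were left out. The peaks on chromosome Y and on unplaced scaffolds were left out of comparisons with genes.

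A peak was assigned to gene ends if any part lay within 1 kb of an end, otherwise to the inside of a gene if it overlapped one, otherwise to the space between genes. Chance was estimated by placing each peak 1000 times at random on its chromosome with its width kept, between 3 Mb and the last gene or peak. Assembly gaps inside that range were not left out. The two-sided p is the share of placements at least as far from their mean as the observed value, with 0.001 as the smallest possible. Alternatives were a circular shift of all peaks of a chromosome and, added after the data were seen, a shift of each peak by 10 to 100 kb to either side, which keeps the neighbourhood. For gene lists, that shift was also made with peaks within 10 kb of each other moved together. Overlap of the lists meant at least 1 bp. The lists were compared with each other by two-sided Fisher's exact tests.

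Of the gene lists, 15 were fixed before the data were examined, and genes with a peak within 5 kb of an end were compared with a background of 21530 protein-coding and listed genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 15 lists and a threshold of 0.05. Such a test treats genes as independent, which clustered families are not. Median scores were compared by permutation tests with 100000 resamples, chromosome counts by a chi-square statistic with 10000 multinomial draws against the span from 3 Mb to the last gene or peak, and densities over the 19 autosomes by correlations with permutation p-values.

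Named genes followed a rule written before the data were examined. For the Adnp list it took the 10 protein-coding genes with the highest score within 1 kb of an end, and for the HP1γ list the 10 with most peaks within 10 kb. It also took the 10 genes with most peaks inside them per list, up to 4 members of each gene list with a peak within 5 kb, and 10 genes with both kinds of peak within 5 kb; ties went alphabetically. The planned wording of the rule named transcription starts, and gene ends took their place. A gene that the rule names is not reported here.

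The alternatives tried were gene ends of 500 bp and 5 kb, protein-coding genes alone, peak centres, autosomes alone, the higher-scoring part of the Adnp list, peaks within 10 kb joined, an overlap of at least 50% of the shorter peak, peak centres within 1 kb and 10 kb, and windows of 1 kb and 20 kb for gene lists. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The placement test was tested on simulated lists: of 40 random lists of the size of the Adnp list 2 were called, and of 40 of the size of the HP1γ list 0. In the gene list test, 6 of 200 random gene lists were called for Adnp peaks and 7 of 200 for HP1γ peaks, among 21523 genes. All 50 planted genes were recovered for each, but a peak was set at the start of each, so this was certain beforehand. The simulated peaks were placed at random, without the clustering of the real lists. These rates therefore do not describe the tests on clustered peaks.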

Results

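The series profiled mouse embryonic stem cells of 1 isogenic background, kept in the pluripotent state in 2i medium with LIF. The labels describe 82 samples in 32 groups: 26 ChIP-seq libraries with 26 matched input libraries, 22 RNA-seq libraries and 8 ATAC-seq libraries. ChIP-seq of tagged proteins was directed at Adnp, a zinc finger and homeodomain protein, and at the heterochromatin proteins HP1α, HP1β and HP1γ, encoded by Cbx5, Cbx1 and Cbx3, and other ChIP-seq used an antibody to the histone mark H3K9me3. The values analysed here are 2 peak lists. The first list holds 15026 Adnp peaks and is tied by the series description to 3 Adnp ChIP replicates in wild-type cells. The second holds 2047 HP1γ peaks without the Adnp motif and is tied to 3 HP1γ replicates in wild-type cells and 3 in Adnp knockout cells. Each list is pooled, so no value has an error between replicates. The units of the tests are peaks, genes for the gene lists and chromosomes for the density correlations. Sequencing depth is unknown, since neither list gives read counts, and the intervals given cover counting error only. The other assays were not analysed here.

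Adnp peaks were narrow, with a median width of 396 bp (quartiles 328 and 481 bp), and the list covered 6470 kb in all. HP1γ peaks had a median width of 306 bp (quartiles 233 and 452 bp) and covered 789 kb. On chromosomes 1 to 19 and X there were 15009 Adnp peaks and 2000 HP1γ peaks, and these entered the comparisons with genes. All positions are on mm10 (GRCm38).

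The first question was where Adnp peaks lie relative to genes. Of the 15009 Adnp peaks, 13.2% (95% Wilson interval 12.6% to 13.7%) lay within 1 kb of either end of an annotated gene, 50.6% (49.8% to 51.4%) lay inside a gene away from its ends, and 36.3% (35.5% to 37.1%) lay between genes. Peaks placed at random on the same chromosomes lay at gene ends in 7.75% of cases, inside genes in 45.2% and between genes in 47.1%. Adnp peaks were thus 1.70 times as frequent at gene ends, 1.12 times as frequent inside genes and 0.771 times as frequent between genes as placed peaks. Each of these differences had a two-sided permutation p = 0.001, the smallest that 1000 placements can give. The excess at gene ends was absent against peaks moved within their neighbourhood, a comparison made only with all genes and ends of 1 kb. Starts and other ends of genes could not be told apart in it. When each peak was moved by 10 to 100 kb to either side, 13.3% of the moved peaks lay at gene ends, and the observed share was 0.987 times that value (permutation p = 0.562).

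Among the Adnp peaks with high authors' scores within 1 kb of an end of a protein-coding gene was 1 at Rfwd3, which encodes a ubiquitin ligase of DNA repair. The Rfwd3 peak spanned 111300481 to 111302189 on chromosome 8, with a score of 417. A peak at 119546848 to 119547365 on chromosome 2, with a score of 315, lay within 1 kb of the neighbouring ends of Exd1 and Chp1, inside Exd1. Ndufa3, a subunit gene of respiratory complex I, shared a peak with a score of 280 with its neighbour Oscar on chromosome 7. Vti1a and Zdhhc6 on chromosome 19 shared a peak with a score of 200. Igfbp4 on chromosome 11 and Lrch1 on chromosome 14 followed with scores of 197 and 187. Some long genes held many Adnp peaks. Dnah8, an axonemal dynein gene on chromosome 17 (30626935 to 30875762), held 26 peaks. Fry on chromosome 5 held 22, Pitpnc1 on chromosome 11 held 18 and Mtus2 on chromosome 5 held 17. B3glct, Cdh13 and Gtf2ird1 each held 13, Cacna1a and Gse1 each held 12, and Dst held 11.

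HP1γ peaks without the Adnp motif had another distribution. Of the 2000 HP1γ peaks, 15.2% (95% Wilson interval 13.6% to 16.8%) lay at gene ends, against 7.38% of placed peaks (2.05 times, permutation p = 0.001, the smallest possible). The share was also above that of peaks moved by 10 to 100 kb, which was 10.6% (1.42 times, permutation p = 0.001). A share of 37.6% (35.5% to 39.7%) lay inside genes, 0.835 times the 45.0% of placed peaks (permutation p = 0.001). Between genes lay 47.3% (45.1% to 49.5%), against 47.6% of placed peaks (permutation p = 0.761). With protein-coding genes alone, HP1γ peaks were 2.54 times as frequent at gene ends as placed peaks.

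Runs of HP1γ peaks marked a small number of protein-coding genes. Tmem267 on chromosome 13 (119488086 to 119610459) had 10 HP1γ peaks within 10 kb of its ends and 8 inside the gene. Cops7a on chromosome 6, a COP9 signalosome subunit gene, had 6 within 10 kb, as did Il3ra on chromosome 14, the gene of an interleukin receptor chain, and Tmppe on chromosome 9. Atf1, Crlf2 and Trim24 had 5 each. Asmt, a melatonin synthesis gene near the distal end of chromosome X (170672644 to 170678054), had 4, all within 1 kb of its ends. Ankrd10 and Adrb3 on chromosome 8 had 4 each. Inside genes, Glb1 on chromosome 9 and Ppm1b on chromosome 17 held 7 HP1γ peaks each, and Cep57l1 and Trak1 held 6 each. Tmppe (114401095 to 114411201) lies within Glb1 (114401078 to 114474379), and its 6 peaks were among the 7 of Glb1. Ezr, Il3ra, Trim24, Xkr6 and Zyg11b held 5 each.

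**Figure D1:**
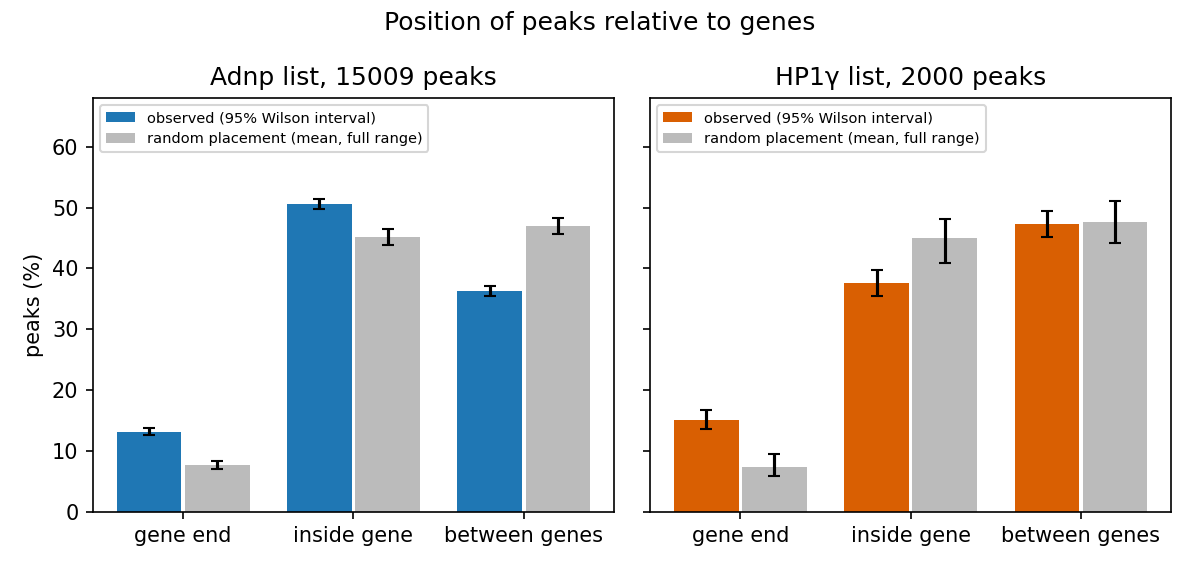
Share of Adnp peaks (left, 15009 peaks) and HP1γ peaks (right, 2000 peaks) in percent at gene ends, inside genes and between genes. Coloured bars show the observed share with its 95% Wilson interval and grey bars the mean of 1000 random placements with its full range. Adnp peaks exceed placement at gene ends and inside genes, and HP1γ peaks exceed it at gene ends only (15.2% against 7.38%).

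Set side by side, the Adnp list held more peaks inside genes than the HP1γ list (odds ratio 1.70, adjusted p = 1.59e-27, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 3 classes) and fewer between genes (odds ratio 0.634, adjusted p = 5.54e-21). At gene ends the Adnp share was lower (odds ratio 0.849, p = 0.0159 in the same exact test). That last direction depended on the window. By Fisher's exact test, the odds ratio was 1.38 (p = 3.86e-11) with gene ends of 5 kb, and 1.21 (p = 0.0064) when peaks within 10 kb of each other were counted as 1 region. Randomly placed joined regions already differed in this direction, lying at gene ends in 11.3% of cases for Adnp and 8.42% for HP1γ. Relative to placement, the joined HP1γ regions remained higher (1.94 times against 1.70 times). With gene ends of 5 kb, Adnp peaks were the higher ones relative to placement too (1.72 times against 1.45 times). The HP1γ list was selected by the authors to lack the Adnp motif, so the contrast describes those selected peaks.

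The next comparison asked how often HP1γ peaks that lack the motif still lie on Adnp peaks. Of the 2000 HP1γ peaks, 303 (15.2%, 95% Wilson interval 13.6% to 16.8%) overlapped an Adnp peak by at least 1 bp. Randomly placed HP1γ peaks did so in 0.51% of cases, with 1.05% in the highest of 1000 placements, so the observed share was 29.7 times the placed mean (permutation p = 0.001, the smallest possible). Moving each HP1γ peak by 10 to 100 kb gave 1.15%, and the observed share was 13.2 times as high. Seen from the other side, 293 Adnp peaks (1.95%) overlapped an HP1γ peak. Their median score of 21.0 differed from the 21.2 of the other Adnp peaks by less than chance rearrangement gives (p = 0.851, two-sided permutation test). Their quartiles lay farther apart, at 12.3 and 39.3 against 13.9 and 33.6. With the Adnp list cut at its score quartiles, 2.26%, 1.65%, 1.49% and 2.40% of peaks overlapped, from lowest to highest scores. A comparison of medians cannot show such a spread, and no test was made on it. HP1γ peaks on Adnp peaks lay at gene ends in 15.5% of cases and the other HP1γ peaks in 15.1% (odds ratio 1.03, p = 0.862, two-sided Fisher's exact test). The names of the HP1γ peaks point to Adnp knockout cells, so the overlap does not show that both proteins lay there in the same cells.

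**Figure D2:**
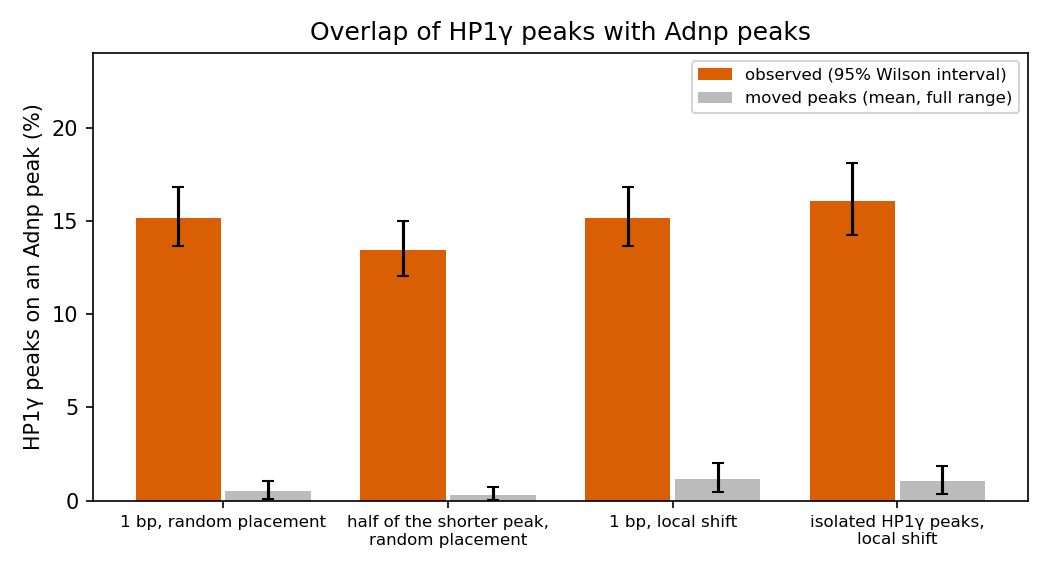
Percent of HP1γ peaks that overlap an Adnp peak. Coloured bars show the observed share with its 95% Wilson interval, and grey bars the mean and full range after moving the HP1γ peaks 1000 times, at random within their chromosome or by 10 to 100 kb. The observed share is 13.5% to 16.1% in the settings drawn, and no set of moved peaks exceeds 2.00%.

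Protein-coding genes with both kinds of peak within 5 kb of an end numbered 187, where 84.7 would be shared if the 4154 genes with an Adnp peak and the 439 genes with an HP1γ peak were independent. This expectation ignores gene neighbourhoods, and no test was made on it. Il3ra had 3 Adnp and 6 HP1γ peaks, and Crlf2, a cytokine receptor gene on chromosome 5, had 1 and 5. Dhrs13 on chromosome 11 had 4 Adnp peaks and 1 HP1γ peak. Haus4 on chromosome 14, a spindle augmin subunit gene, had 3 and 2. Wdr5 on chromosome 2, which encodes a subunit of histone methyltransferase complexes, had 3 and 2, and an Adnp peak there at 27512272 to 27512678 overlapped an HP1γ peak at 27512154 to 27512603. Tmppe, Zscan5b, Catsperg1, Dnah8 and Epp13 also belonged to the 10 genes with most peaks of both lists.

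Genes of the pluripotency network were more frequent near Adnp peaks than other genes in the test within 5 kb. Of 24 pluripotency genes, 12 (50%) had an Adnp peak within 5 kb of an end, against 19.3% of the other genes in a background of 21530 (odds ratio 4.19, adjusted p = 0.00346, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 15 lists). Nanog, a core pluripotency factor on chromosome 6 (122707489 to 122714633), had 6 such peaks, the highest at 122710213 to 122710801 inside the gene with a score of 49.2. The peak of Klf2, a pluripotency factor on chromosome 8, lay at 72326521 to 72327125, beyond the gene, with a score of 138. Dppa5a and Dppa4, genes expressed in the early embryo, had top scores of 58.8 and 42. Peaks moved by 10 to 100 kb lay near 11 of the 24 genes on average, so the observed 12 were 1.09 times that number (adjusted p = 0.898), where all 21530 genes gave 0.978 times. That shift breaks up clusters of peaks. With peaks within 10 kb of each other moved together, the ratio was 1.42 (0.333), where all genes gave 1.12. The call was also lost with a window of 1 kb, where 4 genes had a peak and the odds ratio stayed at 3.53 (0.128), and with peaks inside the gene (odds ratio 1.92, 0.198). Whether these genes exceed their neighbourhoods was therefore not settled.

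A further 3 lists had more genes near Adnp peaks than the background. In the list of heterochromatin and ChAHP genes it was 8 of 19 (42.1%, odds ratio 3.05, adjusted p = 0.0283), among them Pogz, Cbx1, Chd3 and Ehmt2, with top scores of 65.5, 38.9, 33.3 and 30.4. In the list of ribosomal protein genes it was 26 of 83 (31.3%, odds ratio 1.91, adjusted p = 0.0147), with top scores of 111 at Rps10 and 67.5 at Rpl13. In the zinc finger list it was 102 of 428 (23.8%, odds ratio 1.32, adjusted p = 0.0283), with Zfp689 highest at 331, followed by Zfp13, Zfp423 and Zfp647 at 110, 103 and 100.2. Moving peaks by 10 to 100 kb gave ratios of 1.04, 1.15 and 1.03 in the same order (adjusted p = 1, 0.688 and 0.898). With neighbouring peaks moved together they were 1.19, 1.38 and 1.18 (0.695, 0.26 and 0.26). A window of 1 kb left odds ratios of 2.07, 2.15 and 1.24 with fewer genes, and these also did not pass (0.417, 0.128 and 0.417). With a window of 20 kb the zinc finger list did not pass either (odds ratio 1.25, 0.055), while the first 2 lists kept their calls (5.36 and 3.98; 0.00455 and 1.72e-08). Counting peaks inside the gene, 4 of 83 ribosomal protein genes had one (odds ratio 0.194, adjusted p = 0.000377). The odds ratios were 2.24 for the heterochromatin and ChAHP list (0.168) and 0.894 for the zinc finger list (0.498). That test did not allow for gene length. Named ribosomal protein genes were short, such as Rpl13 (123102350 to 123105244), so their low share cannot be told apart from small gene size.

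Clustered gene families and imprinted genes had fewer Adnp peaks than other genes. A peak lay near 5 of 1109 olfactory receptor genes (0.451%, adjusted p = 2.35e-95) and 2 of 352 vomeronasal receptor genes (0.568%, adjusted p = 3.63e-29). It lay near 2 of 57 clustered protocadherin genes (3.51%, adjusted p = 0.00402), Pcdhga8 and Pcdhgb4, which share 1 peak. Of 39 Hox cluster genes, Hoxa9 alone had a peak (2.56%, adjusted p = 0.00824), inside the gene at 52225316 to 52225751 on chromosome 6. Of 67 histone genes, 4 had a peak (5.97%, adjusted p = 0.00824): H1f6, H4c3, H2ac12 and H2bc12. None of 30 imprinted genes had one (adjusted p = 0.00824). Against placed peaks, which keep gene clusters together, both receptor families kept their calls (adjusted p = 0.018 and 0.0321 with circular shifts, 0.003 for each with random placement). The imprinted, protocadherin and Hox lists stayed lower but did not pass. Their ratios were 0, 0.565 and 0.301 with circular shifts (0.275, 0.943 and 0.83) and 0, 0.482 and 0.251 with random placement (0.15, 0.774 and 0.524), with 4.15 or fewer genes expected in each. The 4 histone genes were 1.44 times the number from circular shifts and 1.26 times that from random placement (0.897 and 0.986). All 21530 genes gave 2.15 and 1.76 times, so the histone ratios stayed below those of genes in general. The imprinted, protocadherin, Hox and histone lists stayed lower but were not called with windows of 1 kb and 20 kb. None of their genes had a peak at 1 kb, and the odds ratios at 20 kb ran from 0.491 to 0.832. With peaks inside the gene, the Hox (odds ratio 0.101, adjusted p = 0.00705) and histone lists (0.0579, 2.8e-05) kept their calls. The imprinted list, with 4 of 30 genes (0.59, 0.573), and the protocadherin list, with 10 of 57 (0.816, 0.627), did not. The test inside genes did not allow for gene length. Short genes such as H1f6 (23695811 to 23696545) leave little room for a peak, so the kept calls cannot show depletion. With peaks moved by 10 to 100 kb, singly or with their neighbours, olfactory receptors alone kept their call (0.015 and 0.03).

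Markers of differentiated lineages did not pass the test near Adnp peaks. The counts were 4 of 23 endoderm genes (Gata4, Foxa3, Amn and Sox17; adjusted p = 1), 2 of 21 mesoderm genes (Mesp1 and Hand1; 0.506) and 1 of 22 neural genes (Tubb3; 0.14). They were 2 of 18 trophectoderm genes (Hand1 and Tead4; 0.609) and 5 of 20 germline genes (0.609). The highest score among them was 106 at Mesp1, a regulator of cardiac mesoderm. With a window of 20 kb the neural list was lower, with 3 of 22 genes (odds ratio 0.225, adjusted p = 0.0207). Against circular shifts the germline list was higher (3.29 times, adjusted p = 0.03), where all 21530 genes gave 2.15 times. It did not pass against random placement (2.69 times, adjusted p = 0.0835), where all genes gave 1.76 times. Nor did it pass against peaks moved within their neighbourhood singly (1.14 times, adjusted p = 0.898) or with their neighbours (1.23 times, adjusted p = 0.796).

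Imprinted genes were more frequent near HP1γ peaks than other genes. Of the 30 imprinted genes, which are expressed from 1 parental copy, 11 (36.7%) had an HP1γ peak within 5 kb of an end, against 2.00% of other genes (odds ratio 28.3, adjusted p = 1.39e-10). The imprinted antisense RNA gene Airn on chromosome 17 had 2, the first at 12741140 to 12741439 over the gene's lower end at 12741311. Peg10 and Sgce on chromosome 6, which lie next to each other, shared 2, both inside Peg10, the nearest to its end at 4747568 to 4747777. Igf2 on chromosome 7 had 2 outside the gene, the nearest at 142669664 to 142670247. The other 7, named after their values were seen, were H19, Kcnq1ot1, Mest, Nap1l5, Nnat, Plagl1 and Zrsr1. The count was 25.2 times that of randomly placed peaks and 6.05 times that of peaks moved by 10 to 100 kb, which put 1.82 of the genes near a peak, and the call was kept (adjusted p = 0.015), as it was with neighbouring peaks moved together (7.19 times, 0.015).

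Meiosis and germ cell genes and zinc finger genes were also more frequent near HP1γ peaks. Of 20 germline genes, 3 (15.0%) had a peak: Dazl, Hormad1 and Mael (odds ratio 8.47, adjusted p = 0.0283). Each of these peaks lay within 1 kb of a gene end, at 50292957 to 50293779 on chromosome 17 for Dazl, 95559608 to 95559806 on chromosome 3 for Hormad1 and 166238460 to 166238671 on chromosome 1 for Mael. Of 428 zinc finger genes, 25 (5.84%) had a peak (odds ratio 3.08, adjusted p = 2.37e-05), with Zfp160 on chromosome 17 and Zfp11 on chromosome 5 at 2 each. Olfactory receptor genes were less frequent, with 6 of 1109 (0.541%, odds ratio 0.249, adjusted p = 0.000223). With peaks moved by 10 to 100 kb, these 3 lists did not pass. The germline count was still 6.12 times that of moved peaks (3 genes against 0.49, adjusted p = 0.0899), while the ratio was 1.24 for zinc finger genes (0.702) and 0.572 for olfactory receptor genes (0.536). With neighbouring peaks moved together the ratios were 5.64, 1.52 and 0.615 (0.0949, 0.0949 and 0.501). The germline list also did not pass with a window of 20 kb (odds ratio 4, adjusted p = 0.0818), nor the olfactory receptor list with circular shifts (ratio 0.687, adjusted p = 1) and random placement (0.607, 0.791).

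No gene of the pluripotency, endoderm, mesoderm, neural, heterochromatin and ChAHP, clustered protocadherin, Hox cluster or ribosomal protein lists had an HP1γ peak within 5 kb of an end. These lists did not pass the test, since about 2% of the background had one and few members were to be found by chance (adjusted p of 0.902 for ribosomal protein genes and 1 for the others). The trophectoderm list had 1 of 18, Krt8 (adjusted p = 0.845), the histone list 1 of 67, H2bc14 (1), and the vomeronasal receptor list 4 of 352 (0.845).

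**Figure D3:**
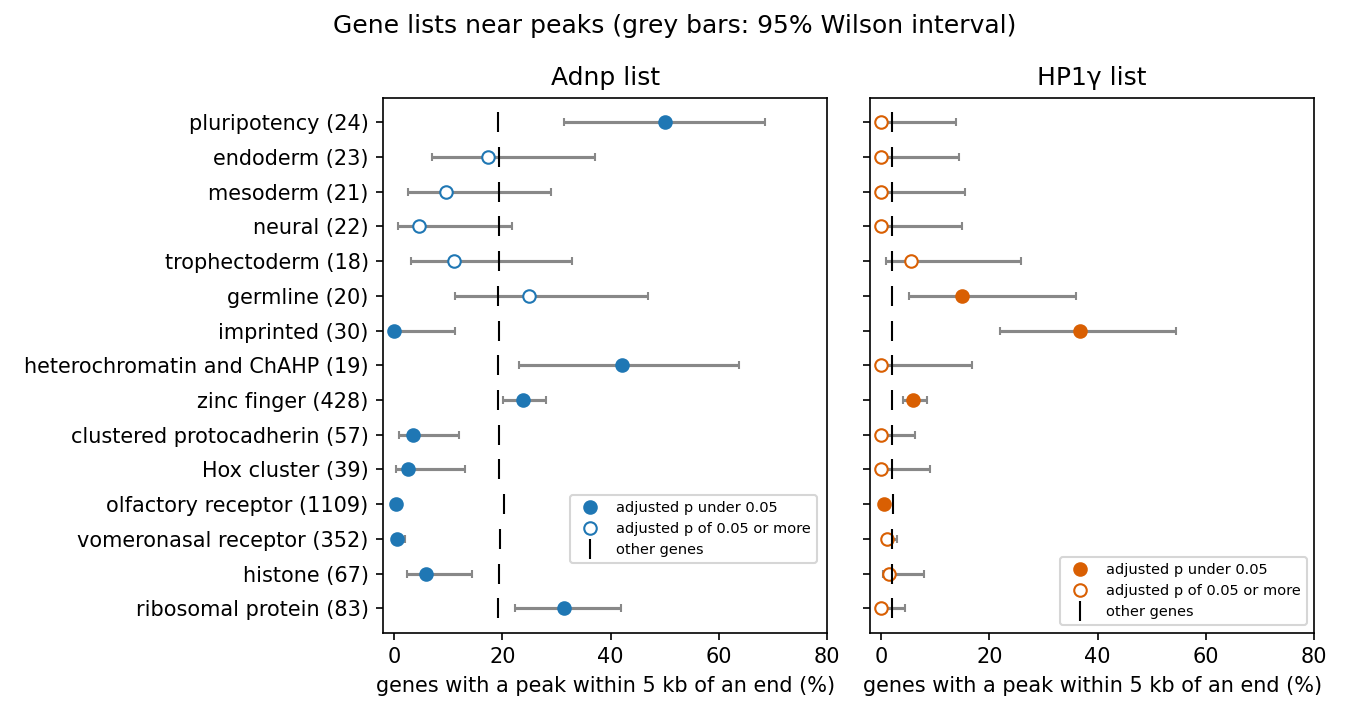
Percent of the genes in each list with an Adnp peak (left) or an HP1γ peak (right) within 5 kb of an end; the number of genes stands in parentheses. Points show the share with its 95% Wilson interval, filled where the adjusted p is under 0.05, and black ticks the share of all other genes. Pluripotency genes reach 50% near Adnp peaks and imprinted genes 36.7% near HP1γ peaks.

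Chromosomes differed in how many peaks they carried. Chromosome 11 had the densest Adnp peaks, with 1365 peaks or 11.5 per Mb (95% Poisson interval 10.9 to 12.1), and chromosome 3 the sparsest among autosomes, with 3.52 per Mb (3.23 to 3.82). Chromosome X had 106 Adnp peaks, or 0.632 per Mb (0.518 to 0.765). HP1γ peaks were densest on chromosome 8 (1.41 per Mb, 1.21 to 1.63) and chromosome 6 (1.33 per Mb, 1.15 to 1.53). Chromosome X had 6 HP1γ peaks, or 0.0358 per Mb (0.0131 to 0.0779). Both lists departed from a uniform density (chi-square 2289 for Adnp and 355 for HP1γ, each p = 0.0001, the smallest that 10000 draws can give), and still did so on the autosomes alone (1371 and 214).

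Over the 19 autosomes, Adnp density rose with the density of protein-coding genes (Pearson's r = 0.708, p = 0.00077, adjusted 0.00231; Spearman's rho = 0.825, p = 4e-05, adjusted 0.00012; permutation tests, 3 relations in the family). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.688. HP1γ density showed no such relation (r = 0.0244, p = 0.923, adjusted 0.923; rho = 0.158, p = 0.516, adjusted 0.516), and it was 0.0758 without the same chromosomes. HP1γ and Adnp densities were not detectably related either (r = 0.269, p = 0.267, adjusted 0.401; rho = 0.333, p = 0.164, adjusted 0.246), with r = 0.388 without chromosomes 5 and 11. Whether the relation with gene density differed between the lists was not tested.

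**Figure D4:**
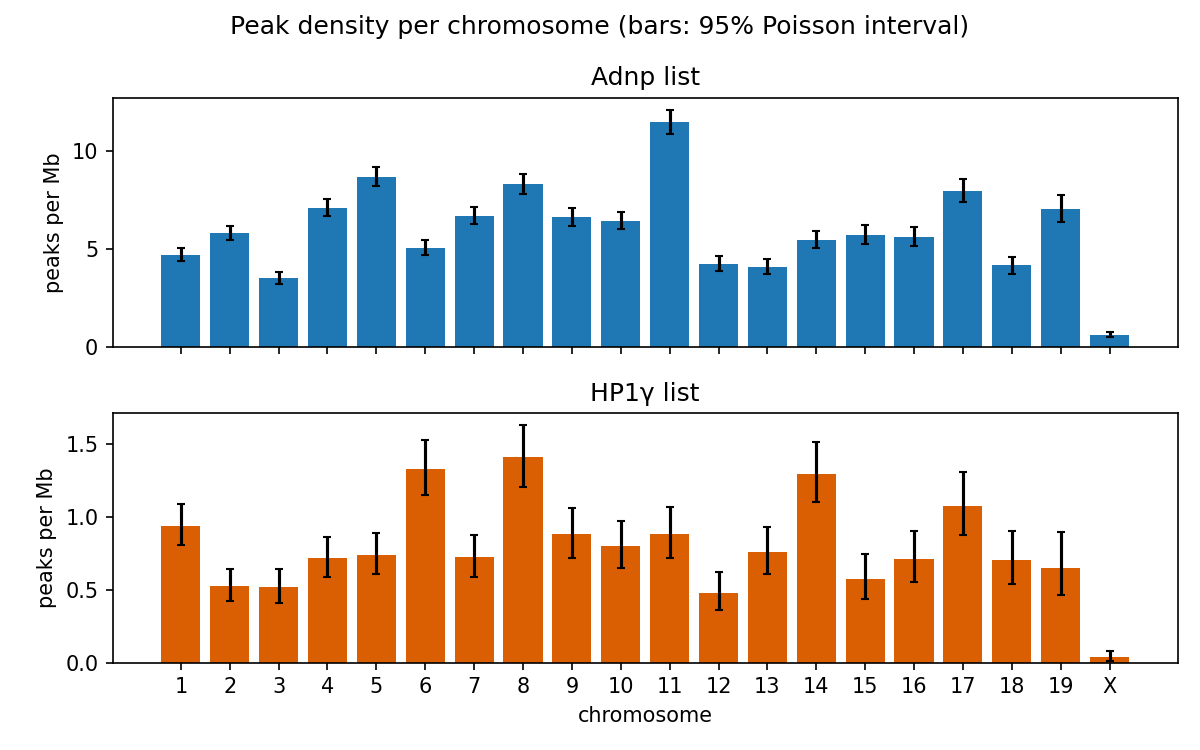
Peaks per Mb on each chromosome for the Adnp list (top) and the HP1γ list (bottom), with 95% Poisson intervals. Adnp density is highest on chromosome 11 (11.5 per Mb), HP1γ density on chromosome 8 (1.41 per Mb), and both are lowest on chromosome X.

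Peaks of both lists ran in clusters. Another Adnp peak lay within 10 kb of 44.6% of Adnp peaks, against 13% after random placement, and another HP1γ peak within 10 kb of 30.4% of HP1γ peaks, against 1.87% (both permutation p = 0.001). Joining peaks within 10 kb of each other left 10839 Adnp regions and 1623 HP1γ regions. The densest Mb of Adnp peaks lay at 107 to 108 Mb on chromosome 11, with 64 peaks among the genes Pitpnc1, Helz, Bptf, Nol11 and Psmd12. The Mb from 132 to 133 on chromosome 4, with Epb41, Eya3 and Phactr4, held 57. For HP1γ, 37 to 38 Mb on chromosome 6 held 16 peaks around Creb3l2, Akr1d1 and Trim24, and 136 to 137 Mb on chromosome 6 held 10 around Atf7ip.

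The authors' score was slightly higher at gene ends. The 1976 Adnp peaks within 1 kb of a gene end had a median score of 22.2 (quartiles 14.6 and 35.7), and the other 13033 peaks one of 21.1 (13.9 and 33.4), a difference of 1.11 (p = 0.00408, two-sided permutation test with 100000 resamples). With gene ends of 5 kb the difference was 0.187 (permutation p = 0.297).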

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

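The tests on gene numbers and on the numbers in the peak names were chosen only after the result was seen, as was the use of shifts by 10 to 100 kb.

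Peaks in places that no comparison above used were found in both lists. The Adnp list had 12 peaks on unplaced scaffolds and 5 on chromosome Y, and the HP1γ list had 31 on unplaced scaffolds and 16 on chromosome Y. The scaffold share was 1.51% of the HP1γ list and 0.0799% of the Adnp list (odds ratio 19.2, p = 8.08e-20, two-sided Fisher's exact test). That test counts neighbouring peaks as independent, so its p-value is too small. Of the 31 HP1γ peaks, 16 lay between 270 and 26283 on the scaffold GL456370 and 8 between 15723 and 36016 on GL456216. The lists shared some contigs: the scaffold GL456370 carried 16 HP1γ and 5 Adnp peaks, and the chromosome 4 scaffold GL456216 carried 8 and 5. On chromosome Y, peaks of both lists lay near its end, from 90725685 to 90813845.

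The overlap of HP1γ peaks that lack the Adnp motif with Adnp peaks was weighed against 2 technical explanations. If both lists merely lay in the same gene-rich neighbourhoods, shifted HP1γ peaks would overlap nearly as often, but the observed share was 7.58 times the highest of 1000 shifts. If clustered peaks had been counted many times, isolated HP1γ peaks would not stand out, but among the 1393 with no other HP1γ peak within 10 kb, 16.1% overlapped an Adnp peak, 8.62 times the highest of their shifts. Sites that attract reads in any such ChIP, or a shared effect of the streptavidin capture, stay open, since no input or control track was used here. The names of the HP1γ peaks point to Adnp knockout cells, so whether both proteins lay at these sites in the same cells is not known, and no biological explanation was tested.

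Chromosome X carried few Adnp peaks, and also few HP1γ peaks, which were 0.0591 of those expected from its share of genes. Its number of genes cannot account for the few Adnp peaks, since they were 0.139 of those expected from its share of genes. Nor can the step that reduced the Adnp list. The numbers in the peak names follow the contigs in order, and they leave room for at most 306 Adnp peaks on X before the list was reduced, 0.193 of those expected. Between 30886 and 31174, the first and last number seen on X, 36.7% of numbers were listed, against 48.4% on the autosomes. Lower coverage of a single X copy cannot be told apart from biology. The directions were those predicted for lower coverage. X held 0.663% of the higher-scoring part of the Adnp list and 0.75% of the lower-scoring part, a difference that was not tested. The median score on X differed by -1.83 from the autosomes, but with 106 peaks this is within chance (permutation p = 0.279). How scores follow depth is not known here. The labels give no sex for the cells, and no biological explanation was tested.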

How the results depend on the processing

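The shifts by 10 to 100 kb of single or joined peaks, the isolated peaks, the list without unsorted peaks and the gene-number weights were chosen only after the data were seen; the rest was fixed before. No paired analysis was possible because each file is 1 pooled list with no values per replicate, and for the same reason no replicate was left out. Depth is unknown, so its limits cannot be stated. Settings that need exons, sequence, strand or soft-masked bases, and those ranking HP1γ peaks by score, were not run. Shifted peaks gave no value for mesoderm and Hox cluster genes near HP1γ peaks.

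The excess at gene ends kept its direction and call from 1.65 to 1.95 times placement for Adnp and from 1.42 to 2.54 times for HP1γ, except for Adnp under shifts by 10 to 100 kb (0.987), whose construction keeps peaks in their neighbourhood. The overlap stayed called from 7.55% (higher-scoring Adnp peaks) to 35.1% (centres within 10 kb), and the chromosome tests and gene context kept every call. The odds ratio of Adnp to HP1γ peaks at gene ends stayed from 0.719 to 0.868 but was 1.38 at 5 kb and 1.21 with joined regions. Placed Adnp regions also lay at gene ends more often than placed HP1γ regions (11.3% against 8.42%). The score difference fell to 0.187 at 5 kb. The cause of the other changes was not tested.

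Of the 4 lists higher and 6 lower near Adnp peaks, the counts were 0 and 2 at 1 kb, 3 and 3 at 20 kb, 0 and 5 inside genes, 5 and 2 with circular shifts, 4 and 2 with random placement, and 0 and 1 with shifts by 10 to 100 kb, of single or joined peaks. Of the 3 higher and 1 lower near HP1γ peaks, they were 2 and 1 at 20 kb, 3 and 2 inside genes, 3 and 0 with circular shifts and random placement, and 1 and 0 with either shift by 10 to 100 kb. Single lists changed direction, as odds ratios against other genes or as ratios to moved peaks, which are different references. Near Adnp peaks, inside genes gave 1.35 for endoderm, 0.894 for zinc finger and 0.194 for ribosomal protein genes (adjusted p = 0.000377), and 20 kb gave 1.43 for trophectoderm. Circular shifts gave 1.82 for endoderm, 1.01 for mesoderm, 1.45 for trophectoderm and 1.44 for histone genes, where all 21530 genes gave 2.15. Random placement gave 1.51 (endoderm), 1.25 (trophectoderm) and 1.26 (histone), where all genes gave 1.76. These ratios therefore stayed below those of genes in general, as in the main test. Shifts by 10 to 100 kb gave 1.36 for endoderm (1.59 with joined peaks), above the 0.978 (1.12) of all genes. Near HP1γ peaks, trophectoderm gave 0 at 1 kb and inside genes and 0.939 at 20 kb. Histone genes gave 1.29 at 20 kb, 2.21 with circular shifts (all genes 1.66) and 1.83 with random placement (all genes 1.41). Inside genes gave 1.47 for pluripotency and 1.54 for endoderm, and circular shifts 1.02 for vomeronasal receptor genes (all genes 1.66). Apart from ribosomal protein genes, none of these passed the threshold. The test inside genes did not allow for gene length, and the cause of these changes was otherwise not tested. Of the other single-list comparisons, 161 were unchanged in call, 50 lost theirs and 3 gained one: neural (20 kb) and germline genes (circular shifts) near Adnp peaks, and vomeronasal receptor genes (inside genes) near HP1γ peaks.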

Other observations

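The tests in this part, on RNA gene types, pseudoautosomal counterparts, the X end and the file order, were all chosen after the data were seen, though the threshold for the tRNA test was set before its result.

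Some Adnp peaks sat on transfer RNA genes. Of 403 tRNA genes, 18 (4.47%) overlapped an Adnp peak, where random placement gave 1.15 on average and shifts by 10 to 100 kb gave 3.37 (permutation p = 0.001 for each, the smallest possible). The neighbourhood of tRNA genes cannot account for all of this, since the count was 1.64 times the highest of 1000 shifts, which was 11. The genes are spread over 8 chromosomes and include n-TRtct4 on chromosome 11, with a score of 40.9, n-TGtcc1 on chromosome 1, with 39.6, and n-TLaag4 on chromosome 7, with 37.3. The genes n-TLaag7 and n-TLaag5 share the peak at 21169888 to 21170441 on chromosome 13. Whether these are sites that attract reads in any such ChIP was not tested, since no input or control track was used. No tRNA gene overlapped an HP1γ peak, where 0.295 would by shifted peaks. Other small RNA genes gave no excess of Adnp peaks, with 3 of 1330 snoRNA genes (permutation p = 0.634 against random placement), 4 of 1228 miRNA genes (p = 1) and 3 of 996 snRNA genes (p = 1).

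HP1γ peaks were frequent in a chosen set of 8 genes whose human counterparts lie in the pseudoautosomal region of the sex chromosomes. Of the 6 genes of this set with a position, 4 (66.7%) had an HP1γ peak within 5 kb of an end. Of the other protein-coding genes, 2.02% had one (p = 2.48e-06, two-sided Fisher's exact test). The 4 genes were Il3ra with 6 peaks, Crlf2 with 5, Asmt with 4 and Csf2ra with 1, while Gtpbp6 and Plcxd1 had none. Adnp peaks lay near 3 of the 6 (p = 0.0904, same exact test). The genes were looked up because Il3ra, Crlf2 and Asmt stood among those with the most peaks, so the p-value is not independent evidence. Whether the set holds all such counterparts was not checked, so the share of 66.7% describes these genes only. The other named counterparts, Dhrsx and Cd99, are placed on unnamed chromosome 4 scaffolds in the gene table, at 14351 to 36213 and 48 to 1475. The 8 HP1γ peaks and 5 Adnp peaks of the chromosome 4 scaffold GL456216 ran from 15681 to 36016, and 2 HP1γ peaks lay from 109 to 1633 on JH584295, but the table does not say that these are the same scaffolds.

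Of the 6 HP1γ peaks on chromosome X, 5 lay beyond 169685199, where Mid1 begins near the X end, and 4 of these lay at Asmt. None of the 106 Adnp peaks lay there, and the last ended at 166478418.

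In the Adnp list, 359 peaks stood at the end of the file outside its sorted order. Their median score was 16.5, against 21.3 for the 14667 sorted peaks.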
